A study of Mus musculus with 14 samples.

How the data were processed

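Gene expression was measured in 14 samples of mouse liver, 1 oligonucleotide array per sample. Per the labels, total RNA was isolated with TRIzol and purified further on RNeasy columns, and biotin-labelled cRNA was prepared by the Affymetrix 3′ in vitro transcription protocol from 100 ng of RNA. The authors deposited 1 intensity per probe set and array on a linear scale. Per the submitters' processing notes, MAS5 and GCOS, the Affymetrix programs that summarise the probes of a probe set into a signal, were used. Their versions, the scaling target and any masking of probe sets are not given in the sources used here, and detection calls were not used here. The deposited intensities ran from 0.0312 to 27760 over 45101 probe sets, of which 64 were control probe sets and entered no test of genes.

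The array medians of the deposited intensity ran from 34.5 in WT control replicate 2 to 53.4 in WT tunicamycin replicate 1. On the log2 scale they differed by 0.63. A rule set before the data were examined called for quantile normalization where array medians differed by more than 0.5 on that scale. The log2 intensities were therefore quantile normalized. Levels and fold changes are on the normalized scale unless deposited values or another setting are named. The ratios of 3′ to 5′ control signal come from the deposited intensities. No depth of reading exists for arrays, and the number of arrays limits the precision.

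Genes were named from the platform annotation: 34945 probe sets had 1 gene, 932 had several and 9160 had none named here. Probe sets without a single gene were left out of the tests of genes and lists. The gene identifiers of 34741 of the probe sets with 1 gene were found in the RefSeq gene table, and 0 symbols had to be updated. A probe set was kept where at least 3 arrays, the size of the smallest group, exceeded the pooled median (log2 5.37, an intensity of 41.5). This left 25316 probe sets, 21808 of them with 1 gene. Each of the 12085 genes was represented by its kept probe set with the highest mean over the arrays. No genome build is given in the sources used here, and no coordinates are printed.

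Group means of the 4 groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend in mean expression), so that 10 residual degrees of freedom were shared by 5 two-sided contrasts: tunicamycin against control in WT and in lsPERK liver, lsPERK against WT under control and under tunicamycin, and the difference between both tunicamycin responses (lsPERK minus WT). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. All adjusted p-values of genes come from these limma fits. A fold change whose lower group averaged under the filter threshold is given as "at least", with the lower group's arrays raised to that threshold. Gene lists (48, fixed before the data were examined) were tested in the 5 contrasts with limma's camera at its preset correlation between genes of 0.01, adjusted over the 240 combinations. Camera with an estimated correlation and fry were run as alternatives. Each list carries the number of its measured genes called higher or lower, and the same number adjusted over the list alone. Python 3.11.15 and matplotlib 3.10.9 drew the figures.

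The text names, per contrast, the 8 called genes higher and the 8 lower whose 95% confidence limit lay farthest from 0, a fixed set of stress response and liver genes, up to 4 members per described list in order of p, Xist and Y-linked genes, and genes with an array far from the others of its group. Genes outside that rule are named as chosen after their values were seen. The replicate numbers in the labels carry no statement of a shared litter, day or animal, and the main fits have no block.

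The procedure was tested on simulated data in which 100 genes per size and comparison, among 12085, were given a known change. Of changes of log2 1, it recovered 54% in the WT response, 51% in the lsPERK response, 48% in the control comparison, 54% in the tunicamycin comparison and 20% in the difference of responses. Of changes of log2 2 it recovered 85%, 87%, 83%, 90% and 76%. False calls made up 3.36% to 6.76% of the calls. The simulated values were independent between genes, had as many rises as falls and were drawn after normalization, filter and choice of probe set. These rates therefore do not cover those steps, correlated genes or a response as broad as the 46.7% of genes called in WT liver.

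The alternatives set before the data were examined covered other filters, values as deposited, median centring of the arrays, an added or floor value at the pooled 25th percentile, other variance models, other rules for several probe sets per gene, a minimum fold change, a 3′ to 5′ signal covariate from the Gapdh and β-actin control probe sets, the replicate number as a block, and each array left out in turn. Alternatives by Xist signal, and without 2 arrays of high 3′ to 5′ signal, were chosen after seeing the data.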

Results

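Livers of wild-type (WT) mice and of lsPERK mice, the knock-out genotype of the series, were profiled 6 h after 1 mg/kg tunicamycin or with 0.3% DMSO as the control. The labels give no time for the DMSO controls, so a difference in the time of collection between treated and control samples is not excluded. Tunicamycin blocks N-linked glycosylation and so causes stress of the endoplasmic reticulum (ER). PERK, encoded by Eif2ak3, is the ER-resident kinase that phosphorylates eIF2 in the unfolded protein response, and the series asks how its loss alters that response, including activation of the transcription factor ATF6. The groups held 3 WT control, 4 WT tunicamycin, 3 lsPERK control and 4 lsPERK tunicamycin arrays. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples. Every group holds arrays with and without Xist signal, so none consists only of repeats of 1 animal, while repeats within those parts are not excluded.

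Across all kept genes, arrays of the same group correlated at r = 0.938 to 0.975 (18 pairs) and arrays of different groups at r = 0.869 to 0.965 (73 pairs), and no pair shared more than 0.0044% of identical values. The first principal component held 39.8% of the variance and ordered the arrays from the controls of both genotypes through lsPERK tunicamycin to WT tunicamycin. The next component held 18% and followed Xist, the RNA that coats the inactive X chromosome of females. Deposited Xist signal was 7878 to 9297 on 6 arrays and 23.4 to 61.2 on the other 8. The deposited signal of the Y-linked Eif2s3y was 0.509 to 14.1 on those 6 and 604.6 to 1313 on those 8. Xist-high arrays made up 1 of 3 in WT control, 1 of 4 in WT tunicamycin, 2 of 3 in lsPERK control and 2 of 4 in lsPERK tunicamycin, and no sex is given in the labels. The log2 ratio of 3′ to 5′ β-actin signal, a measure of RNA integrity, was 1.09 ± 0.15 (SD, n = 3) in WT control, 0.84 ± 0.25 (n = 4) in WT tunicamycin, 0.87 ± 0.25 (n = 3) in lsPERK control and 0.68 ± 0.10 (n = 4) in lsPERK tunicamycin.

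**Figure D1:**
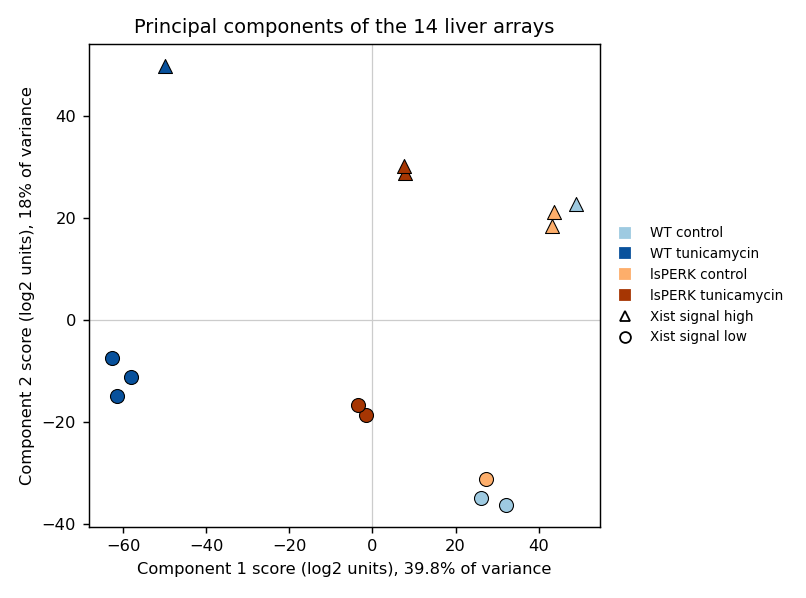
Principal component scores (log2 units) of the 14 arrays, coloured by group, with triangles for Xist-high and circles for Xist-low arrays. Component 1 (39.8% of the variance) runs from WT tunicamycin to the controls of both genotypes, and component 2 (18%) separates the 6 Xist-high from the 8 Xist-low arrays.

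Eif2ak3, the targeted gene, was lower in lsPERK than in WT liver after tunicamycin and rose in both genotypes. Its brighter kept probe set read 338 in WT control (240 to 443 on 3 arrays), 1900 in WT tunicamycin (1720 to 2420 on 4), 140 in lsPERK control (127 to 157 on 3) and 281 in lsPERK tunicamycin (239 to 316 on 4). Between tunicamycin groups the log2 difference was −2.75 (SE 0.18, limma adjusted p = 1.47e-07). Between control groups it was −1.28, with an adjusted p of 0.309. The other kept probe set averaged 6.07 in WT control, 54.3 in WT tunicamycin, 3.04 in lsPERK control and 25.5 in lsPERK tunicamycin. The labels do not say which part of the gene was deleted, and a probe set outside that part checks nothing about the genotype.

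In WT liver tunicamycin raised the genes of the integrated stress response. ER chaperones and genes of transport from ER to Golgi rose, and genes of fatty acid oxidation, of bile acid synthesis and transport and of coagulation fell, at camera's preset correlation. These 5 lists lost the call with an estimated correlation (adjusted p = 0.1, 0.230, 0.535, 0.514 and 0.230). Ddit3, which encodes the stress transcription factor CHOP, rose from log2 7.88 ± 0.27 (SD, n = 3) to 13.99 ± 0.07 (n = 4), a 69.3-fold change (log2 6.12, SE 0.15, limma adjusted p = 5.56e-12). Atf3 rose 203-fold, Trib3, a pseudokinase that restrains Akt signalling, 63.4-fold, and Derl3, a component of ER-associated degradation, 82.5-fold. Nupr1, Psat1 of serine synthesis, the secretory-cell transcription factor Bhlha15 and the phosphatase Dusp8 rose from control levels under the filter threshold, by at least 108-fold, 42.8-fold, 27.7-fold and 14.6-fold. Among the genes with large falls were Acot3 (32.1-fold), Paqr7 (22.8-fold), Depp1 (18.5-fold), Rnf186 (at least 12.8-fold), Gas1 (log2 −3.79) and the carboxylesterases Ces1d (12-fold) and Ces1g (11.5-fold). Tlr12 fell to a level under the filter threshold, by at least 2.83-fold.

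Of the 27 measured ATF4 and integrated stress response genes, 20 rose and 1 fell (21 and 1 adjusted over the list alone), with a median log2 change of 1.79 (camera adjusted p = 1.17e-10). Atf4 itself rose by log2 1.86 (SE 0.18), Ppp1r15a, a subunit of the phosphatase that reverses eIF2 phosphorylation, by 3.39 (SE 0.13), and Asns, Chac1 and Fgf21 by 3.25 (SE 0.86), 3.42 (SE 0.52) and 5.23 (SE 0.47). Vldlr did not pass (log2 0.41, adjusted p = 0.325), though 1 of its 6 kept probe sets was called higher when each was tested. Among 19 cytosolic aminoacyl-tRNA synthetases 17 rose and 1 fell (17 and 1 adjusted over the list alone), among them Wars (log2 2.27), Rars (1.58) and Iars (1.54). That list had a median of 0.98 (camera adjusted p = 1.81e-09, but adjusted p = 0.0694 with an estimated correlation).

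Of 28 ER chaperones and folding enzymes 25 rose and 1 fell (26 and 2 adjusted over the list alone). Their median log2 change was 1.49 (camera adjusted p = 1.53e-17, but adjusted p = 0.1 with an estimated correlation). Creld2 rose by log2 4.33 (SE 0.10), Sdf2l1 by 5.37 (SE 0.24), Pdia4 by 3.08, Ero1a by 2.54, Hyou1 by 2.23, Hspa5, the chaperone BiP, by 1.26 (SE 0.08) and Hsp90b1 by 1.08. IRE1-XBP1 targets rose in 35 of 36 cases with 0 falling (35 and 0 adjusted over the list alone), as in Hspa13 (log2 2.19), Fkbp11 (2.84), Srp19 (1.41) and Dnajb9 (1.90). Their median was 1.04 (camera adjusted p = 2.2e-20, but adjusted p = 0.0696 with an estimated correlation). Many members of this list also stand in another ER list, such as Hspa13, Fkbp11 and Dnajb9 among the ER chaperones. Others are shared with the lists of ER-associated degradation, transport from ER to Golgi or N-glycosylation, so these lists are not independent of each other. Among 27 ER-associated degradation genes 19 rose and 4 fell (19 and 4 adjusted over the list alone). Syvn1 stood at log2 3.40, Sel1l at 2.47 and Edem1 at 1.57, with a median of 0.80 (camera adjusted p = 7.35e-08, but adjusted p = 0.0694 with an estimated correlation). Genes of protein transport from ER to Golgi rose in 26 of 32 cases and fell in 2 (27 and 2 adjusted over the list alone). Tmed3 stood at log2 2.21 (list median 0.92, camera adjusted p = 8.73e-11, but adjusted p = 0.230 with an estimated correlation). Of the stress sensors, Atf6 rose by log2 1.21 (SE 0.17), Ern1, which encodes IRE1, by 1.31 and Xbp1 by 0.63.

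Among 13 reported targets of IRE1-dependent mRNA decay, 7 fell and 0 rose (7 and 0 adjusted over the list alone), among them Ces1d, Pdk2 (log2 −1.22) and Tapbp (−1.19). Their median was −1.07 (camera adjusted p = 0.00176, but adjusted p = 0.197 with an estimated correlation). Of 22 genes of fatty acid oxidation and ketogenesis 18 fell and 0 rose (19 and 1 adjusted over the list alone), with Ppara, the nuclear receptor that drives this programme, at log2 −1.97 (SE 0.24), Cpt2 at −1.27 and Slc25a20 at −0.84. The list's median was −0.60 (camera adjusted p = 0.00015, but adjusted p = 0.535 with an estimated correlation). Oxidative phosphorylation subunits fell in 30 of 39 cases with 0 rising (33 and 0 adjusted over the list alone), with Sdhd at log2 −0.91 and Ndufa9 at −0.67. Their median was −0.28 (camera adjusted p = 2.2e-07, but adjusted p = 0.404 with an estimated correlation). In the values as deposited that median was −0.08 with 1 gene called lower, against a median of all genes of 0.30, and for fatty acid oxidation it was −0.27 with 7 called lower. Decay targets then stood at −0.51, coagulation factors at −0.13 with 5 called lower and bile acid genes at −0.06 with 8. Coagulation factors fell in 14 of 20 cases with 0 rising (15 and 0 adjusted over the list alone), as in F7 (log2 −1.47). Their median was −0.34 (camera adjusted p = 0.000147, but adjusted p = 0.230 with an estimated correlation). Of 19 genes of bile acid synthesis and transport 9 fell and 2 rose (9 and 2 adjusted over the list alone), among them the sterol transporter Abcg5 (log2 −1.51, SE 0.16). The list's median was −0.27 (camera adjusted p = 0.0186, but adjusted p = 0.514 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 2.37 (SE 0.52), Cebpa by 1.01 on the log2 scale, and Srebf1, a regulator of lipid synthesis, 4-fold.

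Other groups that rose in WT liver were p53 targets and cell cycle inhibitors (9 of 15 higher and 2 lower), immediate early genes (8 of 20 higher and 0 lower) and glucocorticoid-induced genes (9 of 15 higher and 1 lower). Among them were Gadd45a (log2 5.10), Plk3 (2.77), Jun (3.75), Cdkn1a, which encodes the inhibitor p21 (5.25), and Igfbp1 (2.83). Their camera adjusted p-values were 0.00174, 0.00292 and 0.00113, but adjusted p = 0.324, 0.639 and 0.526 with an estimated correlation. N-glycosylation genes rose in 15 of 27 cases and fell in 4, with Gfpt1 at 3.42 (camera adjusted p = 0.000314, but adjusted p = 0.253 with an estimated correlation). Adjusted over each list alone the counts were 9 and 2, 8 and 0, 10 and 1, and 15 and 4. Periportal hepatocyte genes fell in 7 of 13 cases with 0 rising (8 and 0 adjusted over the list alone, camera adjusted p = 0.0456, but adjusted p = 0.609 with an estimated correlation). None of the lists of markers of other cell types passed in either response.

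In all, limma called 5642 of 12085 genes in the WT response, 2496 higher and 3146 lower, of which 1063 and 989 changed at least 2-fold. In the values as deposited, where the median of all genes shifted by 0.30 instead of −0.13, the call was 4337 genes with 3632 higher (83.7%, against 44.2%). The Xist-low arrays alone gave 5116 genes and the Xist-high arrays alone, with 1 array in each WT group, 3043, and the integrated stress response list had a median of 1.81 and 1.43 in these.

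**Figure D2:**
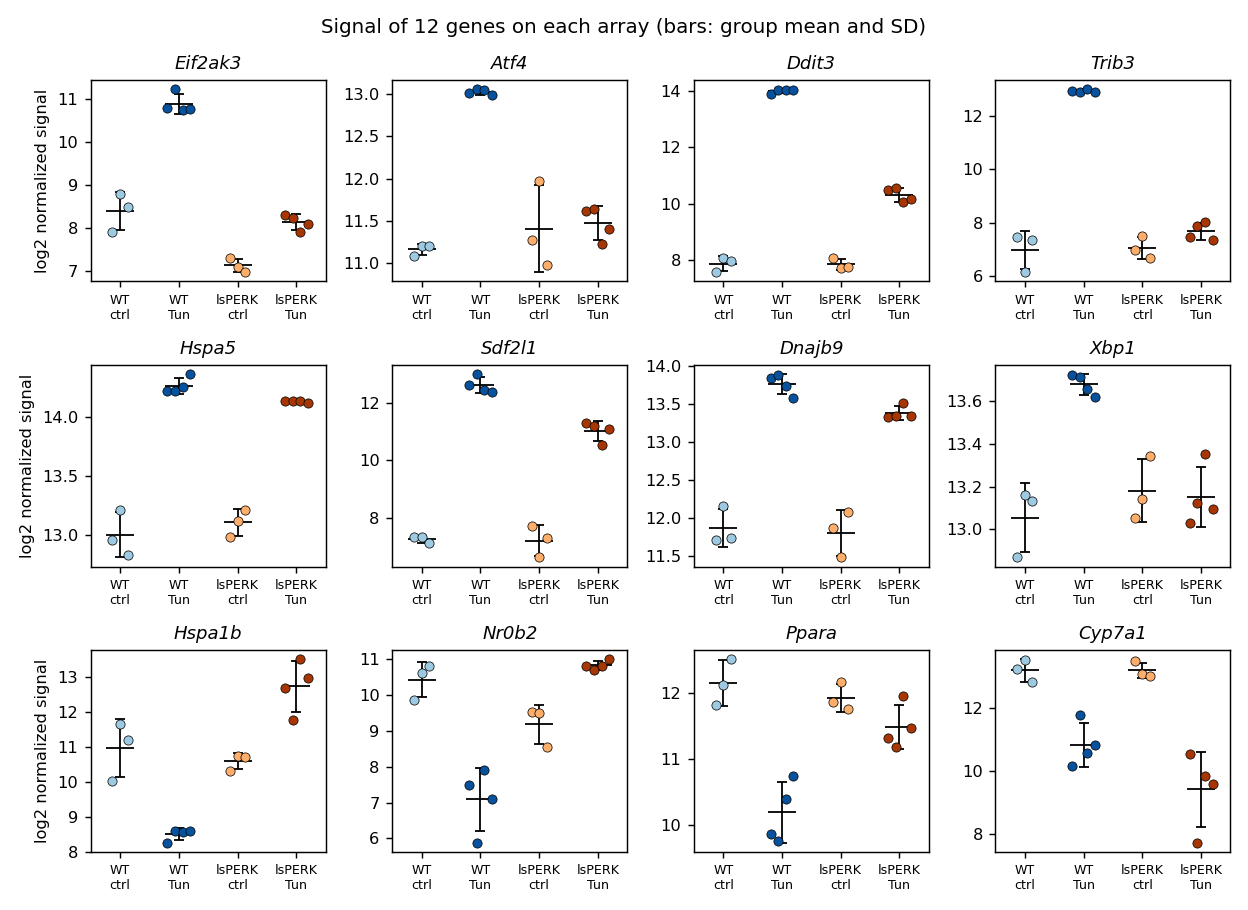
Normalized log2 signal of 12 genes on each of the 14 arrays, by group, with bars for the group mean and SD (n = 3 for controls, n = 4 for tunicamycin). Ddit3 averaged 7.88 in WT control, 13.99 in WT tunicamycin, 7.86 in lsPERK control and 10.31 in lsPERK tunicamycin, while Sdf2l1 averaged 7.25, 12.63, 7.20 and 11.03.

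In lsPERK liver tunicamycin raised the ER chaperones and the IRE1-XBP1 targets, whereas few integrated stress response genes passed the test. Cytosolic heat shock genes rose at camera's preset correlation (adjusted p = 3.83e-09, but adjusted p = 0.0694 with an estimated correlation). Creld2 rose 10.5-fold (log2 3.40, SE 0.10, limma adjusted p = 1.07e-10), Sdf2l1 by log2 3.83 (SE 0.24), Derl3 by 4.01, Bhlha15 at least 20.3-fold and Dusp8 at least 4.29-fold. Egr1, an immediate early transcription factor, rose 17-fold, Zfp9 by log2 3.36 and Igfbp1 by 3.20. Cyp7a1 fell 13.8-fold (log2 −3.79, SE 0.52) and Ces1g 12.9-fold. Further large falls were those of Nrep (log2 −3.53), Retreg3 (−2.72), Tmem238 (−2.69), Limd2 (−2.54) and Ces1d (−2.49), while Zbed5 fell to a level under the filter threshold, by at least 1.15-fold.

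ER chaperones and folding enzymes rose in 25 of 28 cases with 0 falling (25 and 0 adjusted over the list alone), with a median of log2 1.03 (camera adjusted p = 6.02e-30, and 0.0464 with an estimated correlation). Hspa5 rose by log2 1.02 (SE 0.08), Hyou1 by 1.63, Pdia4 by 1.65, Pdia6 by 1.67 and Hspa13 by 2.14. IRE1-XBP1 targets rose in 32 of 36 cases with 0 falling (33 and 0 adjusted over the list alone), with a median of 0.85 (camera adjusted p = 2.92e-34, and 0.0315 with an estimated correlation), as in Fkbp11 (log2 2.74) and Dnajb9 (1.58), while Xbp1 itself stood at −0.03 (adjusted p = 0.882). Of 27 ER-associated degradation genes 14 rose and 1 fell (15 and 2 adjusted over the list alone), with Syvn1 at 2.68. Their median was 0.42 (camera adjusted p = 1.55e-08, but adjusted p = 0.0664 with an estimated correlation). Protein transport from ER to Golgi rose in 24 of 32 genes with 0 falling (28 and 0 adjusted over the list alone), with Sec23b at 1.60. Their median was 0.64 (camera adjusted p = 1.53e-20, but adjusted p = 0.0876 with an estimated correlation). N-glycosylation genes rose in 16 of 27 cases and fell in 1 (17 and 1 adjusted over the list alone), with Gfpt1, the first enzyme of the hexosamine pathway, at 2.13. Their median was 0.50 (camera adjusted p = 2.96e-11, but adjusted p = 0.0542 with an estimated correlation). As in WT liver, these ER lists share members and their calls are not separate results. Atf6 rose by 1.01 (SE 0.17).

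Of the 27 integrated stress response genes 5 rose and 2 fell in lsPERK liver (5 and 2 adjusted over the list alone), with a median of log2 0.07 (camera adjusted p = 0.182). Ddit3 rose by 2.45 (SE 0.15, limma adjusted p = 2.15e-07) and Atf3 by 3.13, whereas Vldlr fell by 1.41. Cytosolic aminoacyl-tRNA synthetases rose in 10 of 19 cases with 0 falling (11 and 0 adjusted over the list alone), among them Nars and Rars (log2 0.75 each). Their median was 0.44 (camera adjusted p = 1.01e-07, but adjusted p = 0.1 with an estimated correlation). Integrated stress response genes that did not pass were Atf4 (0.07, adjusted p = 0.851), Trib3 (0.63, 0.159), Asns (1.66, 0.229), Fgf21 (1.07, 0.152), Nupr1 (at least 0.59, 0.197) and Chac1 (−1.33, 0.107). For Nupr1, 1 of its 2 kept probe sets was called higher when each was tested. Cytosolic heat shock genes rose in 10 of 15 cases with 0 falling (12 and 0 adjusted over the list alone), among them Dnajb4 (log2 1.06), Dnaja1 (0.65), Hsph1 (1.05) and Hspa8 (0.59). Their median was 0.65 (camera adjusted p = 3.83e-09, but adjusted p = 0.0694 with an estimated correlation). Immediate early genes rose in 13 of 20 cases with 0 falling (13 and 1 adjusted over the list alone), as in Egr1, Fos (log2 3.23) and Dusp6 (2.30). Their median was 0.95 (camera adjusted p = 1.05e-07, but adjusted p = 0.307 with an estimated correlation). Of 20 genes of cholesterol synthesis and uptake 7 fell and 0 rose (9 and 0 adjusted over the list alone), among them Fdft1 (log2 −1.62) and Insig1 (−1.08). Their median was −0.75 (camera adjusted p = 1.05e-05, but adjusted p = 0.609 with an estimated correlation). Decay targets of IRE1 fell in 5 of 13 cases with 0 rising (6 and 0 adjusted over the list alone), with Hgsnat at −1.31. Their median was −0.32, and −0.18 with Xist status as a covariate (camera adjusted p = 0.000512, but adjusted p = 0.147 with an estimated correlation). Cebpa fell by 1.23 and Srebf1 by 1.73, and Ppara stood at −0.45 (adjusted p = 0.255). With every kept probe set tested, 2 of 3 for Ppara were called lower.

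In all, 1897 genes were called in the lsPERK response by limma, 1018 higher and 879 lower, of which 274 and 218 changed at least 2-fold. Without lsPERK control replicate 2 the number was 1124, the Xist-low arrays alone, with 1 lsPERK control array, gave 696 and the Xist-high arrays alone 992. Median centring gave 1768 genes with 1142 higher (64.6%, against 53.7%), and the values as deposited gave 695.

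**Figure D3:**
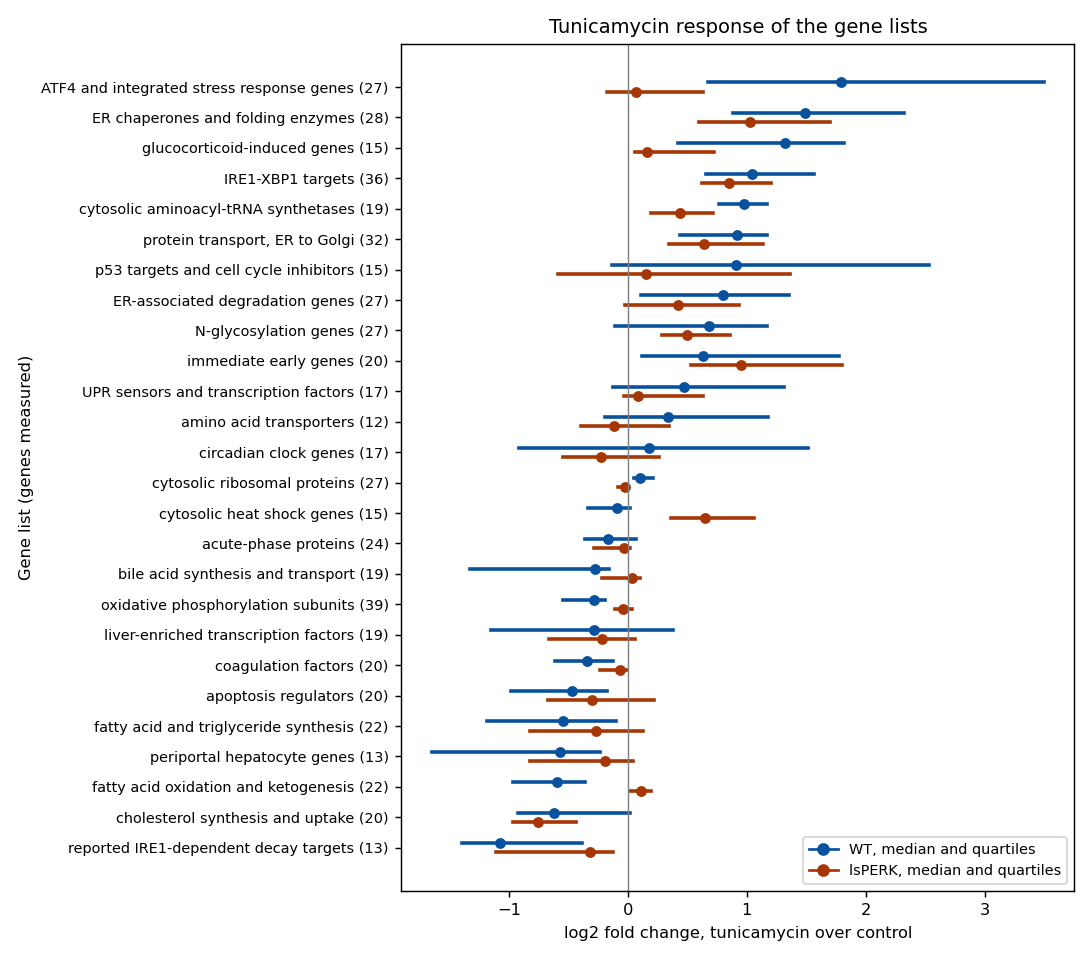
Median log2 fold change (points) and quartiles (lines) of the measured genes of 26 fixed gene lists after tunicamycin, in WT and in lsPERK liver, with the number of genes measured in brackets. The ATF4 and integrated stress response genes have medians of 1.79 and 0.07 and the ER chaperones medians of 1.49 and 1.03, while the ribosomal proteins, near 0, turn negative in WT (−0.17) under median centring.

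In the absence of tunicamycin, no gene passed the limma threshold between lsPERK and WT liver. At an unadjusted p under 0.05 there were 512 genes, and the smallest adjusted p was 0.309, that of Eif2ak3. In WT and lsPERK controls Ddit3 averaged log2 7.88 ± 0.27 and 7.86 ± 0.20, Atf4 11.16 ± 0.06 and 11.41 ± 0.51, and Cyp7a1 13.21 ± 0.36 and 13.21 ± 0.25 (SD, n = 3 each). Other stress genes lay farther apart without passing, such as Asns (log2 −1.65), Chac1 (−0.79), Fgf21 (−0.60) and Gadd45g (1.78), each at an adjusted p of 0.992, and Nupr1 averaged under the filter threshold in both. Of 48 gene lists, 11 passed camera at the preset correlation, with 0 genes called in any of them. The cholesterol synthesis list (median log2 0.23, camera adjusted p = 0.00113), immediate early genes (0.31, 0.00292), p53 targets (0.14, 0.00567), glucocorticoid-induced genes (0.24, 0.0413), sinusoidal endothelial markers (0.19, 0.00566) and female-biased liver genes (2.41, 0.0475) were higher in lsPERK, and so were ribosomal proteins (0.05, 0.000114), whose median turned to −0.15 under median centring. Proteasome subunits (−0.10, 0.000512), fatty acid oxidation genes (−0.12, 0.00825) and bile acid genes (−0.12, 0.0402) were lower, and periportal hepatocyte genes passed upward (0.11, 0.0195) with a mean of −0.05. Without lsPERK control replicate 2 the immediate early genes lost the call (adjusted p = 0.797), and among the Xist-low arrays alone the medians were −0.26 for cholesterol synthesis and uptake and 0.25 for female-biased liver genes. With Xist status as a covariate the bile acid list (−0.03, adjusted p = 0.367), glucocorticoid-induced genes (0.22, 0.095), sinusoidal endothelial markers (0.05, 0.212) and female-biased liver genes (0.22, 0.4) lost the call. In the values as deposited, with all genes at 0.30, the medians of fatty acid oxidation (0.07), bile acid (0.06) and proteasome subunits (0.14) turned positive, and 7 of the 11 lists lost the call, all but fatty acid oxidation, bile acid genes, p53 targets and endothelial markers, and under median centring the periportal (adjusted p = 0.824) and glucocorticoid-induced lists (0.113) did. None of the 11 passed with an estimated correlation, where the lowest adjusted p was 0.397. The number of genes called was 17 among the Xist-low arrays alone, which include 1 lsPERK control array, and 7 among the Xist-high arrays alone, which include 1 WT control array. Eif2ak3 was called without WT control replicate 1 (log2 −1.53, adjusted p = 0.017) and among the Xist-low arrays (−1.66, adjusted p = 0.0153). Nupr1, on signal under the filter threshold, stood at 4.43 among the Xist-high arrays. Without WT control replicate 3 it was called lower (−3.53), but the probe set that stands for a gene is chosen anew when an array is left out. On the probe set of the main fit, with a difference of 2.56, the loss of 1 array cannot give that value. It therefore comes from another probe set of the gene. Angptl8, chosen after its values were seen, was called without lsPERK control replicate 3 (1.90).

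After tunicamycin, the 2 genotypes differed most in the integrated stress response genes, which were lower in lsPERK liver. Nupr1 was 72.2-fold lower in lsPERK (log2 −6.18, SE 0.58, limma adjusted p = 3.56e-06), Chac1 46.7-fold, Trib3 39-fold, the hepatokine Fgf21 27.1-fold and Ddit3 12.8-fold. Tes (log2 −4.17), Slc7a1, a transporter of cationic amino acids (−3.91), and Ddx28 (−3.60) were lower too. Higher in lsPERK were Acot3 (log2 4.30), the cytosolic chaperone Hspa1b (4.24), Nr0b2, the nuclear receptor SHP that represses bile acid synthesis (3.74), Fos (3.43), Paqr7 (3.38), Cldn1 (2.99), Zfp750 (at least 4.41-fold) and Rnf186 (at least 9.35-fold). Of the fixed genes, Atf4 (log2 −1.55), Atf3 (−4.03), Asns (−3.24), Pdia4 (−1.31), Cyp7a1 (−1.42) and Atf6 (−0.43, adjusted p = 0.0457) were lower in lsPERK and Ppara (1.30) was higher. Hspa5 (−0.14, adjusted p = 0.179), Cebpa (−0.10, 0.663) and Srebf1 (0.54, 0.143) did not pass.

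Of 27 integrated stress response genes 21 were lower and 0 higher in lsPERK (23 and 1 adjusted over the list alone), with a median of log2 −1.59 (camera adjusted p = 4.05e-14, and 0.0203 with an estimated correlation). Cytosolic heat shock genes were higher in 13 of 15 cases and lower in 1 (13 and 1 adjusted over the list alone), with a median of 0.76 (camera adjusted p = 6.76e-07, but adjusted p = 0.110 with an estimated correlation). Among 28 ER chaperones 14 were lower and 1 higher (15 and 1 adjusted over the list alone), with a median of −0.29 (camera adjusted p = 0.000314, but adjusted p = 0.609 with an estimated correlation). Under median centring 6 were lower and that median was −0.08 (adjusted p = 0.0584). Limma called 4269 genes between the treated groups, 2238 higher and 2031 lower in lsPERK, 466 and 585 of them by at least 2-fold. The values as deposited gave 2662 with 705 higher (26.5%, against 52.4%), the Xist-low arrays alone 3358, and the Xist-high arrays alone, with 1 WT tunicamycin array, 2070.

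The difference between both responses (lsPERK minus WT) was tested directly and asks which responses to tunicamycin changed with the genotype. It was negative for stress genes that rose in WT liver, led by Trib3 (log2 −5.36, SE 0.40), the GTPase Rnd1 (−4.83, called lower in lsPERK), Chac1 (−4.75), Tes (−4.59), Atf3 (−4.54), Ddit3 (−3.67, SE 0.21, limma adjusted p = 3.39e-07) and Gadd45a (−3.66). Nupr1 was called as well, but both of its control groups averaged under the filter threshold (log2 2.12 and 4.67), so the size of its difference rests on background signal. It stood at −6.18 between the tunicamycin groups. The difference of responses was positive for Nr0b2 (4.98, SE 0.55), Hspa1b (4.62, SE 0.53), Depp1 (4.14), Paqr7 (3.99), Rnf186 (3.84, with a WT tunicamycin level under the filter threshold), Egr1 (3.67), Arrdc3 (3.31) and Gm17753 (3.21). Both of the first named changed in opposite directions: Nr0b2 by log2 −3.33 in WT and 1.65 in lsPERK liver, and Hspa1b by −2.47 and 2.15. Of the fixed genes, Atf6 (−0.19, adjusted p = 0.633), Hspa5 (−0.24, 0.159), Hyou1 (−0.60, 0.155), Dnajb9 (−0.32, 0.284), Herpud1 (−0.30, 0.113), Asns (−1.59, 0.412), Cebpa (−0.22, 0.589), Srebf1 (0.27, 0.707) and Cyp7a1 (−1.42, 0.202) did not pass. These values are of the brightest probe set of each gene. With every kept probe set tested, 2 of 3 for Atf6 and 1 of 3 for Hspa5 were called with a negative difference. Conversely, only 1 of 2 kept probe sets was called for Cpt2, Bdh1, Sdhd, Pdia4, Paqr7 and Eif2ak3. The same held for Cpt2, Pdia4 and Ahsa1 in the WT response and for Pdia4, Bhlha15 and Bmf in the lsPERK response. For these genes 0 probe sets were called in the opposite direction.

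Of 27 integrated stress response genes 19 had a negative difference and 0 a positive one (20 and 0 adjusted over the list alone), with a median difference of log2 −1.79 (camera adjusted p = 1.1e-14, and 0.0203 with an estimated correlation). Aminoacyl-tRNA synthetases were lower in 10 of 19 cases and higher in 1 (11 and 2 adjusted over the list alone), with Wars at −1.54 and Iars at −1.28. Their median was −0.64 (camera adjusted p = 1.22e-05, but adjusted p = 0.175 with an estimated correlation). Among 15 p53 targets and cell cycle inhibitors 8 were lower and 0 higher (8 and 0 adjusted over the list alone), with a median of −0.83 (camera adjusted p = 0.000222, but adjusted p = 0.230 with an estimated correlation). ER-associated degradation genes were lower in 13 of 27 cases and higher in 1 (16 and 5 adjusted over the list alone), with Derl3 at −2.36 and Sel1l at −1.30. Their median was −0.51 (camera adjusted p = 0.0004, but adjusted p = 0.221 with an estimated correlation). ER chaperones were lower in 9 of 28 cases and higher in 0 (9 and 1 adjusted over the list alone), with Ero1a at −1.55, Sdf2l1 at −1.54 and Creld2 at −0.93. Their median was −0.22 (camera adjusted p = 8.68e-05, but adjusted p = 0.563 with an estimated correlation). Under median centring that median was −0.04 (adjusted p = 0.1). Under median centring 7 of the ER-associated degradation genes were lower and 2 higher, with a median of −0.19. IRE1-XBP1 targets were lower in 5 of 36 cases and higher in 0 (4 and 0 adjusted over the list alone), with a median of −0.13 (camera adjusted p = 0.0213, but adjusted p = 0.797 with an estimated correlation) that turned to 0.07 under median centring.

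Cytosolic heat shock genes had a positive difference in 10 of 15 cases and a negative one in 0 (12 and 1 adjusted over the list alone), with Hspa1b and Hspa1a at log2 4.62 each, Dnajb4 at 1.34 and Dnaja1 at 0.64. Their median was 0.64 (camera adjusted p = 6.96e-06, but adjusted p = 0.147 with an estimated correlation). Fatty acid oxidation genes had a positive difference in 13 of 22 cases and a negative one in 0 (15 and 0 adjusted over the list alone), with Cpt2 at 1.47, Ppara at 1.52 and Bdh1 at 1.09. Their median was 0.70 (camera adjusted p = 1.04e-06, but adjusted p = 0.350 with an estimated correlation). For oxidative phosphorylation subunits it was positive in 19 of 39 cases and negative in 0 (25 and 0 adjusted over the list alone), with Ndufb3 at 0.94 and Sdhd at 0.72. Their median was 0.30 (camera adjusted p = 2.38e-08, but adjusted p = 0.358 with an estimated correlation). In the values as deposited that median was 0.04 with 0 genes called, against a median of all genes of −0.42. Heat shock genes then stood at 0.41 with 3 called and fatty acid oxidation at 0.40 with 4. Coagulation factors were positive in 8 of 20 cases and negative in 0 (10 and 0 adjusted over the list alone), with Klkb1 at 0.85 and Serpind1 at 0.70. Their median was 0.26 (camera adjusted p = 0.000833, but adjusted p = 0.324 with an estimated correlation). That median was 0.08 with 1 called in the values as deposited, and 0.65 with 14 called under median centring.

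Limma called 2401 genes in the difference of responses, 1232 positive and 1169 negative, 428 and 549 of them by at least 2-fold. The values as deposited, with the median of all genes at −0.42, gave 1901 with 129 positive (6.79%, against 51.3%). The Xist-low arrays alone gave 1178 genes and the Xist-high arrays alone 671, and the median difference in these was −1.54 and −1.49 for the integrated stress response and 0.80 and 0.56 for heat shock genes.

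Across 12085 genes, which are not independent replicates, the log2 changes of both genotypes correlated with Pearson's r = 0.523 and Spearman's rho = 0.502, and the slope of lsPERK on WT was 0.327. The 2 responses share no arrays. Both called 773 genes higher, where independent lists would share 210, and 636 lower, where they would share 229. The slope through 0 within lists was 0.231 for the integrated stress response, 0.367 for aminoacyl-tRNA synthetases, 0.735 for ER chaperones, 0.826 for IRE1-XBP1 targets, −0.040 for fatty acid oxidation and −0.80 for heat shock genes. Such a slope gives most weight to genes with large WT changes. In the heat shock list, whose WT median was −0.09, these include Hspa1b (log2 −2.47 in WT) and Bag3 (1.74). The Xist-low arrays alone gave r = 0.378, and a stricter filter on dim probe sets 0.606.

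**Figure D4:**
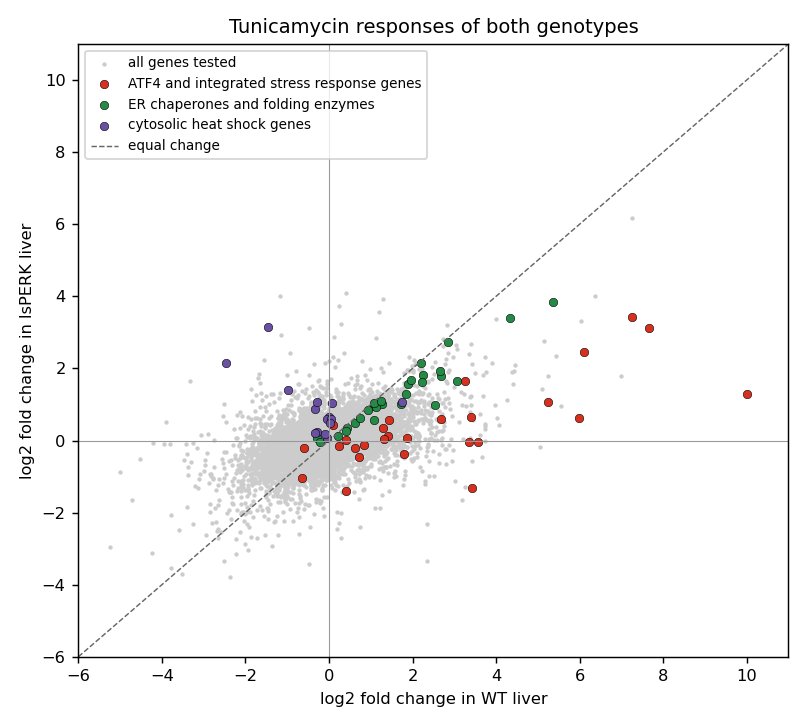
Log2 fold change after tunicamycin in WT (horizontal) and lsPERK liver (vertical) of 12085 genes (grey), with 3 fixed gene lists in colour and a dashed line of equal change. The slope through 0 is 0.231 for the integrated stress response genes, 0.735 for the ER chaperones and −0.80 for the cytosolic heat shock genes. The heat shock list had a WT median of −0.09, so its slope does not describe the list as a whole.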

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

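The splits of the arrays, the covariates and the matched random lists below test explanations written down before their results were seen, except for array scaling. The Xist covariate and the test of array scaling were chosen after seeing the data.

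For some genes 1 array lay far from the other 3 of its group, relative to how closely those 3 agreed. In WT tunicamycin replicate 2, the 1 Xist-high array of its group, these were Xist (log2 13.03), Eif2s3y (1.51), Eif2ak3 (log2 11.24), Tes (11.62), Rnd1 (10.96), Wars (10.44), Rora (12.58) and Pdk2 (8.94). In WT tunicamycin replicate 1 they were Chac1 (12.32), Hspa1b (8.26), Dusp8 (9.49), Tmem238 (8.04) and Fos (7.43), and in WT tunicamycin replicate 4 Plk3 (11.54). In lsPERK tunicamycin they were Dnajb9 (13.52), Cebpa (11.80) and Bmf (4.77) in replicate 3 and Insig1 (11.92) in replicate 1. Of 326 gene and group pairs tested 18 stood out in this way, where chance singles out about 5%, and 14 of the 18 were in WT tunicamycin. The gap itself was small for some, as in Wars (10.44 against 10.53 to 10.54) and Plk3 (11.54 against 11.63 to 11.64).

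A difference between the genotypes in the response to tunicamycin, tested directly (lsPERK minus WT), singled out 2401 genes. Those named here with a negative difference included Eif2ak3 (log2 −1.48), Atf4 (−1.79), Ddit3 (−3.67), Atf3 (−4.54), Trib3 (−5.36), Chac1 (−4.75), Fgf21 (−4.16), Vldlr (−1.82), Ppp1r15a (−2.75), Slc7a1 (−3.65), Wars (−1.54), Iars (−1.28) and Nfil3 (−3.26). Further ones were Gadd45a (−3.66), Tes (−4.59), Rnd1 (−4.83), Rora (−1.58), Sgk1 (−1.93) and Mt2 (−3.46). The value of Nupr1 (−8.73) is not a measured size, since both of its control groups averaged under the filter threshold. In the ER they were Xbp1 (−0.66), Hsp90b1 (−0.53), Pdia4 (−1.43), Dnajc3 (−0.70), Edem1 (−0.93), Creld2 (−0.93), Sdf2l1 (−1.54), Ero1a (−1.55), Sel1l (−1.30) and Derl3 (−2.36). A positive difference stood beside Nr0b2 (4.98), Hspa1b (4.62), Hspa1a (4.62), Dnajb4 (1.34), Dnaja1 (0.64), Depp1 (4.14), Rnf186 (3.84), Arrdc3 (3.31), Egr1 (3.67), Paqr7 (3.99) and Gm17753 (3.21). In metabolism and clotting it stood beside Ppara (1.52), Cpt2 (1.47), Bdh1 (1.09), Ndufb3 (0.94), Sdhd (0.72), Abcg5 (1.57), Klkb1 (0.85) and Serpind1 (0.70).

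Gene lists singled out by the same difference had negative medians for ATF4 and integrated stress response genes (−1.79), amino acid transporters (−0.46), aminoacyl-tRNA synthetases (−0.64), ER chaperones (−0.22), ER-associated degradation (−0.51), IRE1-XBP1 targets (−0.13) and stress sensors (−0.19). So did p53 targets (−0.83), circadian clock genes (−0.50), glucocorticoid-induced genes (−0.83) and ribosomal proteins (−0.12). Medians were positive for fatty acid oxidation (0.70), bile acid genes (0.33), coagulation factors (0.26), heat shock genes (0.64) and oxidative phosphorylation (0.30). The integrated stress response list kept its call with an estimated correlation (adjusted p = 0.0203), and the other 15 lists had adjusted p = 0.124 to 0.821 with it. Under median centring the calls of amino acid transporters, ER chaperones, IRE1-XBP1 targets, stress sensors, glucocorticoid-induced genes and ribosomal proteins were lost (adjusted p = 0.0542 to 0.925). Signal outside the tests of genes was seen as well: of 3508 kept probe sets with no single gene named here, 460 were higher and 538 lower after tunicamycin in WT, and 134 higher and 100 lower in lsPERK liver.

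The count of called genes was compared with other splits of the same arrays. For the WT response 1 of 35 splits reached the real count, the real one itself, and the highest of the others, which exchanged all 3 controls with 3 of the 4 treated arrays, gave 2852 genes. For the lsPERK response it was 1 of 35, with 9 as the highest other. For lsPERK against WT after tunicamycin it was 1 of 35, with 3 as the highest other. For the controls the real count was 0, which all 10 of 10 splits reach by construction, with 3 as the highest; the comparison carries no information, and so few splits could not give a share under 0.05 for any count. For the difference of responses 2 of 100 splits, drawn from 700, reached the real count or exceeded it, 1 of them the real one. The other such split gave 2442 genes, kept the genotypes of the tunicamycin arrays and exchanged 1 control array between the genotypes. The remaining 98 gave 0 to 203. Only that 1 other drawn split kept the tunicamycin genotypes. The low share therefore reflects the difference between the treated groups, and the comparison cannot decide on a difference of responses beyond it. With Xist status as a covariate 1 gene differed between the controls, Id3 (log2 0.89, chosen after its values were seen).

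Heat shock genes had a positive difference of responses (lsPERK minus WT), and 3 technical explanations were set against an effect of the genotype. With Xist status as a covariate the median difference was 0.638, as without it. With the 3′ to 5′ signal ratio as a covariate it was 0.634. The Xist-high share and the mean ratio both fell with tunicamycin by similar, small amounts in each genotype. A covariate with the same effect in all groups could therefore hardly move the difference, and the lists below share this limit. The medians within the Xist-low and the Xist-high arrays alone, given above, stayed positive. A tunicamycin response that depends on the 3′ to 5′ ratio was not modelled. A factor per array moves all genes alike and cannot set a list apart from them. The list therefore stood 0.823 above the median of all genes by construction, both as deposited and under median centring. Quantile normalization is not such a factor, and there the list stood at 0.638 with all genes at 0.084. The distance of the list from all genes thus depended on the scaling. So did its absolute size (0.407 as deposited with 3 genes called instead of 10, and 0.978 under median centring with 12). Both sizes stay open, as does an effect of the genotype, since the call was lost with an estimated correlation (adjusted p = 0.147).

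Fatty acid oxidation genes fell in WT liver and had a positive difference of responses. With Xist status as a covariate the median difference was 0.688, and with the 3′ to 5′ ratio as a covariate it was 0.721. Among 10000 random lists matched in brightness the central 95% of medians ran from −0.105 to 0.311, and the list's 0.7 lay outside. As deposited the median was 0.40 with 4 genes called instead of 13, where all genes stood at −0.42. The list thus lay 0.816 above them, as under median centring by construction, since these scalings differ by a factor per array. On the quantile-normalized scale the list stood at 0.7 and all genes at 0.084. The list lay above all genes on each scale, but its absolute size and its distance from them depended on the scaling. An effect of the genotype stays open, since the call was lost (adjusted p = 0.35 with an estimated correlation).

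Oxidative phosphorylation subunits showed a smaller difference in the same direction. With Xist status as a covariate the median was 0.303, and with the 3′ to 5′ ratio as a covariate it was 0.330. The median of 0.303 lay outside the −0.019 to 0.263 of matched random lists, but that in the WT response (−0.28) lay inside their −0.317 to 0.006. A fall shared by bright probe sets could therefore account for the WT response of this list, while the difference between the genotypes lay just beyond it and lost its call (adjusted p = 0.358 with an estimated correlation). As deposited that difference was 0.04 with 0 genes called, but 0.46 above all genes, as under median centring by construction. On the quantile-normalized scale it was 0.303 with all genes at 0.084, so scaling moved both its absolute size and its distance from all genes.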

How the results depend on the processing

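Alternatives by Xist signal, and without the WT tunicamycin and WT control arrays of highest 3′ to 5′ ratio, were chosen after seeing the data. Of the alternatives set beforehand other than leaving out an array, named genes kept their call in 9720 cases and lost it in 358. They gained it in 40 and reversed in 8. The counts also hold the slope of the lsPERK on the WT response, which has no test. It makes up the 2 cases that moved and some of those kept. A gene called in neither fit counted as kept whatever its direction, so sign changes among such genes are not counted. Gene list tests kept the call in 1050, lost it in 137 and reversed in 3. With 1 array left out the counts (kept, lost, gained, reversed and moved) were 8786, 162, 39, 1 and 0 for genes with that slope. For lists they were 887 kept, 50 lost and 1 reversed. Where no value shows a cause, the cause was not tested.

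Values as deposited gave 695 genes in the lsPERK response, 2662 between the tunicamycin groups and 0.141 for Ahsa1 in WT. Median centring turned Rpl4 (−0.104), Rplp0 (−0.032), Rps7 (−0.108) and the ribosomal list (−0.168) in the WT response, Rpl4 (0.061) and Rplp0 (0.019) between tunicamycin groups, Rpl4 (0.191), Rps7 (0.147) and that list (0.283) in the difference of responses, and that list between controls (−0.148). The correlation between responses was 0.302 with no filter on dim probe sets, 0.364 at the 30th and 0.606 at the 70th percentile. Testing every kept probe set, which tests more features, gave 10253, 3152, 7386 and 3711 calls (WT, lsPERK, tunicamycin groups, difference). Requiring a 2-fold change, a stricter rule, gave 2052, 492, 1051 and 977. Of 240 list tests 67 passed by camera, 5 with an estimated correlation and 78 by directional fry, while fry's mixed test, which ignores direction, passed 134. Between controls 1 gene was called in a fit of these groups alone (Hsd17b13), 1 with the 3′ to 5′ covariate (Slc25a25, both chosen after their values were seen), 1 with the Xist covariate and 1 without the arrays of high ratio (Eif2ak3), where the correlation between responses was 0.447.

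The Xist-low arrays alone, fewer samples, gave 696 genes (lsPERK), 17 (controls) and 1178 (difference), a correlation of 0.378, and control medians of −0.26 for cholesterol synthesis and uptake and 0.25 for female-biased liver genes. The Xist-high arrays alone gave 3043, 992, 7, 2070 and 671 genes (WT, lsPERK, controls, tunicamycin groups, difference), and −0.057 for endothelial markers between controls; a lone array in a group is assumed to vary like the others.

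Leaving out 1 array in turn gave 4895 to 5707 genes (WT), 1124 to 2056 (lsPERK, lowest without lsPERK control replicate 2), 0 to 1 (controls), 3686 to 4367 (tunicamycin groups) and 1941 to 2297 (difference). Eif2ak3 between tunicamycin groups stayed at −2.81 to −2.65 and list tests at 63 to 71. Nupr1 between controls ran from −3.53 to 2.57, but its lowest value, without WT control replicate 3, comes from another probe set of the gene. The control median of immediate early genes ran from 0.06, without lsPERK control replicate 2, where the test's direction reversed, to 0.49. The replicate number as a block gave 5472, 1666, 0, 4256 and 2243 genes, and 6 of 13 pairs matched best by number. The difference of responses was not run in fits of 2 groups, nor list tests over every probe set or with a minimum fold change. Signal over background limits genes near the filter threshold of log2 5.37.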

Other observations

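The genes and lists below come from the fixed lists or, for genes with opposite responses, were chosen after their values were seen.

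Genes of fatty acid and triglyceride synthesis moved in both genotypes without a list call. In WT liver 10 of 22 fell and 2 rose, among them the acyltransferases Gpam (log2 −1.37) and Agpat2 (−1.48), while Insig2 rose by 1.27 (camera adjusted p = 0.0576). In lsPERK liver 6 fell and 1 rose, among them Dgat2 (−0.87) and Srebf1 (−1.73), with Insig2 at 0.94 (camera adjusted p = 0.0552). Of 19 liver-enriched transcription factors 8 fell and 5 rose in WT, including Nr1i3, the xenobiotic receptor CAR (−1.38), and Foxa2 (−1.78) lower and Nfil3 (2.64) higher, and 5 fell and 3 rose in lsPERK. Neither list test passed (camera adjusted p = 0.524 and 0.240).

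Of 20 apoptosis regulators 9 fell and 3 rose in WT and 6 fell and 2 rose in lsPERK liver, and the list passed in neither (camera adjusted p = 0.227 and 0.444). Casp9 fell in WT (log2 −1.71) and the cytokine receptor Tnfrsf12a rose in WT (3.35) and in lsPERK (2.41), where the proapoptotic Bmf (−2.68) and Bbc3 (−1.22) fell. Of 24 acute-phase proteins 9 fell and 4 rose in WT, as in Cfb (−0.60) and Serpina3n (−0.98), and 0 were called in lsPERK. In all, 81 genes were called in opposite directions by genotype, 37 of them higher in WT and lower in lsPERK. That is fewer than independent lists of these sizes would share, and 773 genes were called higher and 636 lower in both. Genes with opposite calls include Rnd1 (3.18 in WT and −1.65 in lsPERK), the chemokine gene Cxcl1 (−1.84 and 1.11), the heat shock gene Hspa4l (−0.77 and 1.18) and Mttp, which loads lipid onto lipoproteins (−0.47 and 0.62).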
